A study of Drosophila melanogaster with 6 samples.

How the data were processed

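Total RNA from 6 ovary samples, 3 wild-type and 3 upSET mutant, was labelled with Cy3 and hybridised to single-colour NimbleGen expression arrays, per the labels' protocols. Images were extracted with NimbleScan 2.4, per the labels' protocols, and RMA is the processing tool named in the submitters' processing notes. RMA corrects background, normalizes arrays to each other and summarises the probes of a target into 1 value, and its version and settings are not given in the sources used here. The design text describes 4 probes of 60 bases for each of 15473 genes, which equals the number of features in the table. The deposited values are on a log scale taken as log2, since they ran from 5.30 to 15.99 on arrays read by a 16-bit scanner. They were not centred per gene. No scanner files, probe values or detection calls were used here, so no feature could be called above or below background. The genome build and the annotation release behind the array are not given in the sources used here. No scan date or slide was used here, so batches could not be looked for.

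The features carry FlyBase transcript identifiers and no gene names. Names came from the synonyms of a RefSeq gene table for Release 6 plus ISO1 MT, in which 44 identifiers of the table were found (0.28%). Of these, 17 belonged to 1 gene and 27 to several genes on 1 transcript, and 15429 features stayed unnamed. Named features were brighter than most. No coordinates are given, because the build of the array is not known to be that of the gene table.

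Groups and replicate numbers came from the sample titles. The design text names the mutation epic and the labels name it upSET; both give an insertion in CG9007, and they were taken as the same gene. The deposited log2 values of all 6 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, no filter on dim features). The log2 change is the upSET mutant minus the wild type, with the moderated standard error. P-values were two-sided and adjusted by Benjamini-Hochberg over 15473 features, with a threshold of 0.05. The limma p-values rest on 3 separate dissections per genotype. The difference in mean level between higher and lower features was tested by a two-sided permutation test with 100000 resamples (20000 in the alternatives). The fit was tested on simulated data, drawn from normal distributions with each feature's mean and within-group spread and with 200 changed features among 15473. There limma recovered 20% of changes of 0.5 on the log2 scale, 66% of changes of 1, 90% of changes of 2 and 100% of changes of 4. There were 9 unchanged features among the 147 called. The data gave 2376 calls, and the adjustment is stricter where fewer features change. The shares recovered in the simulation may therefore lie below those in the data.

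These choices were made before the data were examined: the design, the alternatives, 32 gene lists and the rule for named genes. The rule was to name upSET, the 10 largest changes in each direction past the threshold among features of a single gene with a symbol other than a bare CG or CR number, and the 2 largest in each direction whatever the symbol, all with non-overlapping groups. It added up to 3 members of each list with the smallest adjusted p past 0.05, or the member with the smallest p where none passed. With 44 named features, the rule gave the 4 unnamed transcripts, mio, NaPi-III, kis, HDAC3 and His4r. All other single genes and the shared transcripts past the threshold were added after the data were seen, so that every single-gene feature is reported. Camera tests of the lists needed 5 measured members, and no list had more than 1, so none was run. The tests of neighbouring genes and of genes near upSET, the centring on ribosomal protein genes and the averaging of features of 1 gene could not be run either, for the same reason. Alternatives were quantile normalization, median centring, filters on dim features, a trended and robust variance, array weights, the replicate number as a block, stricter thresholds and leaving out each array. Leaving out features with a mean above 15 was added after the data were seen. Replicate numbers recur in both groups, and the samples were treated as unpaired. Signal over background may limit the precision of dim features, though this was not measured. The number of arrays limits the precision of all features.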

Results

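Gene expression was measured in whole ovaries of 2-day-old Drosophila melanogaster females. One group was the wild-type strain OregonG, and the other was a line in which a piggyBac transposon insertion lies in upSET (CG9007), a gene for a SET-domain chromatin protein. Each group had 3 biological replicates from separate dissections, and each replicate was hybridised to 1 single-colour NimbleGen array, giving 6 arrays in all. The table held 15473 features, each a FlyBase transcript identifier measured by 4 probes of 60 bases. The comparison asked how the ovarian transcriptome of the mutant differs from that of the wild type. The arrays had closely matched distributions, with medians from 11.2 to 11.3 and upper quartiles from 14.1 to 14.2 on the log2 scale. The number of arrays, 3 per group, limits the precision of every value below.

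Arrays of 1 genotype resembled each other more than arrays of different genotypes. Across features, Pearson's r lay between 0.994 and 0.996 within the wild type and between 0.995 and 0.996 within the mutant. Between genotypes all 9 pairs lay between 0.980 and 0.982. These correlations are across features, which are not independent replicates. No 2 arrays were copies of each other, since at most 6 features had identical values in any pair.

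The mutant ovary differed widely from the wild-type ovary, and the largest changes were mostly gains. With limma and Benjamini-Hochberg adjustment, 2376 of 15473 features (15.4%) passed an adjusted p of 0.05, of which 1246 were higher and 1130 lower in the mutant. Over all called features the directions were nearly balanced, with 52.4% higher. The balance tipped toward gains as the size of the change grew. Among features changed at least 2-fold, 694 were higher and 409 lower. Among those changed at least 4-fold, 231 were higher and 72 lower. At 16-fold or more, 40 were higher and 6 lower, and at 32-fold or more, 22 were higher and 3 lower. The groups did not overlap in 2375 of the 2376 called features, and in 32.7% of all features, where chance gives 10% for 3 against 3.

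**Figure D1:**
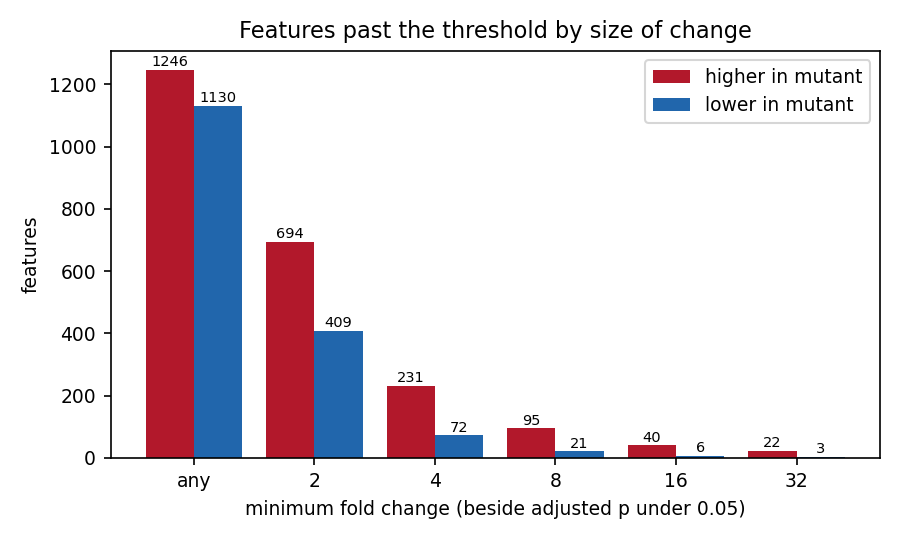
Number of features past an adjusted p of 0.05 (y axis) at increasing minimum fold change (x axis), with bars for features higher and lower in the upSET mutant. Higher features outnumber lower ones by 694 to 409 at 2-fold and by 40 to 6 at 16-fold.

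The split over all called features was near even under each scaling, but which direction held the slight majority changed. Each scaling, RMA included, brings the arrays to a common level. The near-even split and the small median change therefore cannot show whether total expression shifted. Centring each array on its median gave 1150 higher and 1270 lower, and quantile normalization gave 1164 higher and 1259 lower. The excess of gains at 2-fold or more was smaller under both scalings, with 666 higher against 449 lower after median centring and 636 against 486 after quantile normalization, where 694 against 409 were found as deposited. At 16-fold or more the counts hardly moved under both scalings, with 40 higher against 6 lower at 16-fold after median centring and 39 against 6 after quantile normalization. They were 41 against 9 without wild-type replicate 1 and 40 against 8 with array weights. Without any other array they were 38 to 42 against 5 or 6. The median log2 fold change over all features was -0.03 as deposited, -0.07 after median centring and -0.02 after quantile normalization. Without mutant replicate 3, 749 features were lower and 943 higher. The wild type was a separate strain from the mutant line, so the design does not separate the insertion from other differences between the strains. A batch that coincides with genotype could not be looked for either.

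The 2 largest gains and the 2 largest losses in measured intensity ran between levels of 5.79 to 7.30 in one genotype and 12.14 to 14.00 in the other. Transcript FBtr0075181 rose from 5.97 ± 0.10 (SD, n = 3) in the wild type to 13.93 ± 0.23 in the mutant, a log2 change of 7.96 (SE 0.15, limma adjusted p = 8.66e-08). Transcript FBtr0084880 rose from 7.30 ± 0.15 to 14.00 ± 0.08 (log2 change 6.69, SE 0.13, limma adjusted p = 8.66e-08). In the other direction, FBtr0077067 fell from 12.14 ± 0.17 to 5.79 ± 0.20 (log2 change -6.35, SE 0.15, limma adjusted p = 3.12e-07). Transcript FBtr0072881 fell from 12.58 ± 0.20 to 7.04 ± 0.06 (log2 change -5.54, SE 0.14, limma adjusted p = 3.29e-07). The gene names of these 4 transcripts were not paired with their identifiers in the tables used here. Levels near 6 lie at the bottom of the measured range and no detection calls were used here, so these differences and their ranks are of measured intensities, not of transcript amounts.

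Features were grouped by their mean level over both genotypes, so a feature that moves far from the bottom of the scale has a middling mean by construction. The 3868 features with mean levels from 6.52 to 11.19 held 1400 calls, 36.2% of them, 759 higher and 641 lower. The next 3868, from 11.19 to 14.16, held 661 calls (17.1%), 326 higher and 335 lower. The dimmest 3869 features, below 6.52, held 175 calls (4.52%), and the brightest 3868, from 14.16 up, held 140 (3.62%). The SD of the log2 changes was 0.30 in the dimmest set, 1.11 in the second, 0.54 in the third and 0.22 in the brightest. The highest value of any feature was 15.99, next to 16, the log2 ceiling of a 16-bit scanner.

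**Figure D2:**
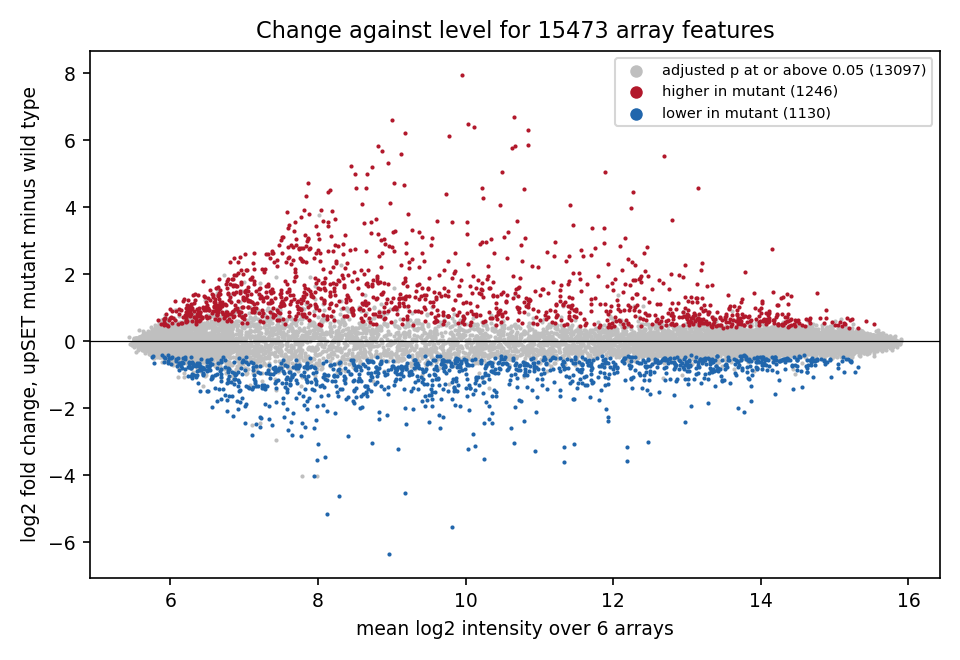
Log2 fold change, upSET mutant minus wild type (y axis), against the mean log2 intensity over the 6 arrays (x axis), with 1 point per feature coloured by call. The 1246 higher and 1130 lower features lie mostly between 6.52 and 14.16, and the spread narrows at both ends.

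Higher features had a lower mean level than lower features, 9.72 ± 2.58 (SD, n = 1246) against 10.16 ± 2.56 (n = 1130). The difference of -0.44 had p = 4e-05 in a two-sided permutation test with 100000 resamples. That test shuffled called features as independent units, so its p does not measure the spread between dissections. Nor were the calls independent, since features with adjacent identifiers tended to be called in the same direction. The difference did not pass in every setting, with -0.18 and p = 0.09 after quantile normalization and -0.22 and p = 0.058 without wild-type replicate 3, each in a permutation test. It was -0.25 without wild-type replicate 2 (permutation p = 0.032) and -0.69 without mutant replicate 1 (permutation p = 5e-05, the smallest that 20000 resamples can give).

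Gene names could be given to 44 of the 15473 features. The level of upSET itself is not among them and was not analysed here, so the labels were not checked against the targeted gene. Of these 44, 5 passed the threshold, 2 higher and 3 lower, a share of 11.4% against 15.4% over all features. No named feature changed by as much as 2-fold, and their log2 changes ran from -0.58 to 0.69. Their median level of 14.21 was above the median of all features, 11.19. Of the brightest 3868 features, from 14.16 up, 3.62% were called, and of the next 3868, 17.1%. In the brightest set 9 called features rose and 6 fell by at least 2-fold. The lack of 2-fold changes is therefore not read as a trait of the named genes. Of the 44, 17 belonged to 1 gene and 27 to transcripts that carry several open reading frames with separate gene names.

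Among the 17 single genes, 2 were lower in the mutant and none was higher by limma at an adjusted p of 0.05. mio, a component of the GATOR2 complex that is needed to maintain oocyte identity, fell from 11.72 ± 0.16 to 11.24 ± 0.06 (SD, n = 3), a log2 change of -0.47 (SE 0.13, limma adjusted p = 0.043). NaPi-III, a phosphate transporter, fell from 15.19 ± 0.08 to 14.67 ± 0.19, a log2 change of -0.52 (SE 0.14, limma adjusted p = 0.038). Wdr24, another GATOR2 component, had a log2 change of 0.32 (SE 0.17, limma adjusted p = 0.28).

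The 4 chromatin genes among the 17, grouped after matching, did not pass the threshold in limma, though 2 of them, SuUR and kis, had an unadjusted p under 0.05. The same held for alpha-Spec and Dyrk3, outside this group, with an unadjusted limma p of 0.045 and 0.037. SuUR, which controls under-replication of heterochromatin in polytene cells, came closest, at 14.02 ± 0.08 in the wild type and 14.58 ± 0.30 in the mutant (SD, n = 3), a log2 change of 0.56 (95% interval 0.19 to 0.94, limma adjusted p = 0.055). kis, a trithorax-group chromatin remodeller, had a log2 change of 0.40 (interval 0.05 to 0.74, limma adjusted p = 0.13). The class I histone deacetylase HDAC3 had a log2 change of 0.19 (interval -0.20 to 0.57, limma adjusted p = 0.55). The replacement histone gene His4r had a log2 change of -0.21 (interval -0.52 to 0.11, limma adjusted p = 0.39). kis, HDAC3 and His4r were the measured members of the lists for trithorax, deacetylase and histone variant genes. No list was tested, and adjusted over the list alone, with 1 member each, the p from limma is the unadjusted one, 0.029, 0.30 and 0.17. Over all features, 4304 of 15473 had an unadjusted p under 0.05.

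The cytoskeletal and matrix genes alpha-Spec and LanA had log2 changes of 0.37 and -0.06. alpha-Spec encodes a spectrin chain found in the fusome of dividing germ cells, and LanA a laminin chain of basement membranes. Their limma adjusted p was 0.17 and 0.88. Uba1, the ubiquitin-activating enzyme, was at 0.13, and rdx, a substrate adaptor of a ubiquitin ligase, at -0.06. The fatty acid transport gene Fatp1 was at -0.16 and the nucleolar gene sle at 0.25. The protein kinase gene Dyrk3 was at -0.51, fend at 0.28, CG16974 at 0.03 and CG31178 at 0.27. None of these 8 passed, with limma adjusted p between 0.15 and 0.93. CG31178, at a mean level of 6.44, lay near the bottom of the scale.

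**Figure D3:**
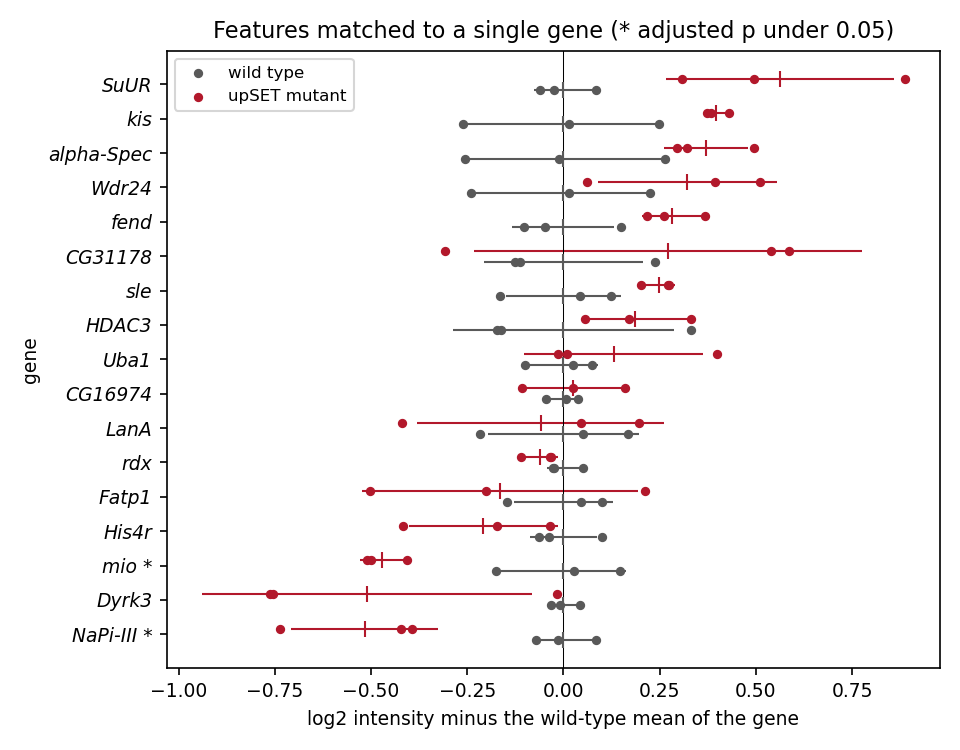
Log2 intensity minus the wild-type mean of the gene (x axis) for the 17 features matched to a single gene (y axis), with 1 point per array and bars for the mean and SD of each group of 3. Only mio and NaPi-III, marked with an asterisk, have an adjusted p under 0.05, and the largest mean gain is that of SuUR at 0.56.

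Of the 27 features on shared transcripts, 2 rose and 1 fell, and each value is that of the whole transcript, so all its gene names are given. The transcript shared by Rad1 and Sws1 rose from 12.88 ± 0.08 to 13.56 ± 0.14 (SD, n = 3), a log2 change of 0.68 (SE 0.13, limma adjusted p = 0.0082). Rad1 encodes a subunit of the checkpoint clamp of the DNA damage response. The transcript shared by Mettl5, a ribosomal RNA methyltransferase gene, and CG42374 fell from 14.54 ± 0.15 to 13.95 ± 0.19, a log2 change of -0.58 (SE 0.14, limma adjusted p = 0.029). The transcript shared by CG17325 and CG42305 rose from 5.62 ± 0.27 to 6.20 ± 0.09 at the bottom of the scale, a log2 change of 0.58 (SE 0.16, limma adjusted p = 0.045).

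Of the 5 calls on named features, that on the Rad1 and Sws1 transcript passed in all 14 other settings, with limma adjusted p from 0.0015 to 0.036. The mio call was lost without any 1 array except wild-type replicate 1 and with trended and robust variance, with limma adjusted p from 0.017 to 0.14 over all settings. The NaPi-III call was lost without any 1 of the 6 arrays, with limma adjusted p from 0.0060 to 0.12 over all settings. The Mettl5 and CG42374 call was lost without wild-type replicate 1 or 3 or mutant replicate 1 or 3, over a range from 0.0056 to 0.10. The CG17325 and CG42305 call was lost without any 1 array except wild-type replicate 1 and with median centring, over a range from 0.013 to 0.13. With the replicate number as a block, 4 of the 5 calls were lost, at limma adjusted p of 0.081 for mio, 0.071 for NaPi-III, 0.082 for the Mettl5 transcript and 0.054 for the CG17325 transcript. SuUR passed in 4 of 14 settings, among them without mutant replicate 3 (log2 change 0.69, limma adjusted p = 0.042, range 0.012 to 0.14). Dyrk3 passed without mutant replicate 2 (log2 change -0.76, limma adjusted p = 0.011, range 0.011 to 0.37), and kis with trended and robust variance (limma adjusted p = 0.039, range 0.039 to 0.27).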

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

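The count of 2376 changed features stayed within 1.5 times under quantile normalization, median centring, a filter on features below the lower quartile of level, trended and robust variance, array weights and, chosen after seeing the data, the removal of features above a mean of 15 (2363 to 2661). An adjusted p under 0.01 gave 1240 features, 728 higher and 512 lower, and a 2-fold minimum gave 1103, 694 higher and 409 lower. Leaving out features below the median level tested fewer features and gave 1148, 533 higher and 615 lower, with 220 changed at least 2-fold. Without each array in turn, the count ran from 1692 to 2178, the higher features from 943 to 1109, the lower ones from 749 to 1069 (749 without mutant replicate 3), and those changed at least 2-fold from 1030 to 1121. The features called both with and without quantile normalization numbered 2259, all in the same direction. The difference in level, -0.44, was -0.18 after quantile normalization and ran from -0.69 to -0.22 without each array; the cause was not tested. Same-numbered arrays did not deviate together (correlations across features -0.036, -0.058 and -0.026), and with the replicate block the count was 1939, 1047 higher and 892 lower. Small changes in 4 genes changed sign. CG16974 was at -0.011 with median centring. Without each array, CG16974 ran from -0.042 to 0.093, LanA from -0.19 to 0.12 (0.024 without wild-type replicate 3), Fatp1 from -0.35 to 0.0052 and Uba1 from -0.0030 to 0.20; the cause was not tested. Over the single genes, the 3 shared transcripts past the threshold and the 4 transcripts without gene names, in the settings that tested each, 286 values kept direction and call, 26 lost a call, 6 gained one and 6 changed sign. Centring on ribosomal protein genes, averaging the features of a gene, and all alternatives for upSET itself, the gene lists, neighbouring genes and genes near upSET were not run, since 44 features had names; log2(value + 16) was not run because the values were already on a log scale. Signal over background may limit small changes at the bottom of the scale, and the scanner ceiling those at the top, but neither limit was measured.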

Other observations

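All tests in this part were chosen after the values were seen. The table had 4598 features with a mean below 7 (29.7%) and 6093 with a mean above 13 (39.4%). A small group crossed from low to high levels with the genotype. In 36 features all 3 wild-type values were below 7 and all 3 mutant values above 9, with medians of 6.11 and 10.10. The reverse held for 6 features, with medians of 10.27 in the wild type and 5.95 in the mutant. With limits of 7 and 10 the counts were 13 and 2. When wild-type replicate 1 was set aside, 45 features met the limits of 7 and 9 for a gain. The reverse was not counted in this way. It may be larger as well. Of 7 features low in that replicate alone among the wild type, 6 were also below 7 in all mutant arrays. The other wild-type arrays were at 9.30 to 12.1 for these 7. With all arrays 1 of the 7 was called, and without that replicate 6 were. The contrast of 36 against 6 may therefore overstate the excess of gains.

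The wide change between the genotypes was set against other groupings and against strain differences linked to upSET. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05; 1 split, the real one, gave 2376 features, the highest other 0, and for changes of at least 2-fold 1 split gave 1103 and the highest other 0. Identifiers served as a rough guide to position, since 33 of 43 consecutive named features lay on the same chromosome arm, where 8.74 were expected (permutation p = 1e-04, the smallest that 10000 permutations can give). The 972 identifiers between the Mettl5 transcript and SuUR, whose genes lie on either side of upSET in Release 6 plus ISO1 MT, held 146 called features (15.02%) against 15.4% of the others (odds ratio 0.973, 95% interval 0.805 to 1.16 from a bootstrap of blocks of 20 identifiers). The called features there included FBtr0075181, the largest change of all. They also held 3 of the 46 features changed at least 16-fold, a share near that outside (odds ratio 1.04, 95% interval 0.206 to 3.26, Fisher's exact p = 0.76). The share of 15.02% argues only against a raised share of calls across this interval. A narrower region around upSET was not tested, and strain differences anywhere in the genome and the insertion in upSET both stay open. A processing batch that coincides with genotype could not be looked for and stays open as well.

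Features with adjacent identifiers were called in the same direction in 330 pairs, where 197 were expected with calls permuted within 20 bins of level. The one-sided permutation p was 1e-04, the smallest that 10000 permutations can give, and 6e-04 after BH adjustment over the 6 distances. The larger distances had 1000 such permutations each. There were 224 pairs against 189 expected at a distance of 2 features and 230 against 185 at 3. Further out there were 193 against 184 at 5, 214 against 183 at 10 and 201 against 180.0 at 20. In that order, the BH-adjusted permutation p was 0.0075, 0.003, 0.25, 0.0075 and 0.0516. The value at 3 rests on the smallest p that 1000 permutations can give. Calls that concentrate at certain levels are argued against as the whole cause, as the ratio of observed to expected pairs was 1.68 with levels matched in this way. Neighbours that vary together between replicates of a genotype are argued against too, as the main source of the neighbour covariance of the log2 changes. Replicate noise, taken within each genotype, accounted for 6.00% of that covariance (95% bootstrap interval 4.39% to 8.02%). A batch that coincides with genotype would not show in that noise, so it stays open. Large changes weigh most in a covariance, so how many of the 330 pairs replicate noise could give was not measured. The same target measured more than once, or copies of a gene, stays open, although the ratio was 1.46 among pairs more than 1 log2 apart in mean level. The design text counts 15473 genes, as many as there are features. Most features could not be named here, so shared targets among neighbours were not checked. No biological explanation was tested.

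In wild-type replicate 1, 7 features lay more than 3 log2 below the mean of the other wild-type arrays. They were at 5.95 to 6.87 against 9.30 to 12.1, and the other wild-type arrays were within 1 log2 of each other. By the same limits, mutant replicate 2 had 3 features above its group and mutant replicate 1 had 1, and the other arrays had 0. With a limit of 2 log2, wild-type replicate 1 had 12 below and 5 above. Mutant replicate 2 then had 2 below and 13 above, and mutant replicate 1 had 3 below and 5 above. In 6 of the 7, all 3 mutant arrays were also below 7, from 5.58 to 6.49, which argues against a defect of that array. Replacement of most of that sample by mutant RNA is argued against too, since at the 45 features below 7 in replicates 2 and 3 and above 9 in all mutants, replicate 1 exceeded the other wild-type arrays by a median of 0.0491% of the mutant level (95% bootstrap interval -0.347% to 0.513%) and by at most 30.2%. Of the 7, 5 had another member within 3 identifiers, where 0.0128 were expected (permutation p = 1e-04, the smallest that 10000 permutations can give). No biological explanation was tested.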
